A study of Bos taurus with 54 samples.

How the data were processed

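Liver samples of 16 Holstein cows were measured on 1-colour Agilent arrays, which read cyanine-3 labelled RNA. Per the labels, the cows belonged to a group with subacute ruminal acidosis (SARA, a fall of rumen pH in the weeks after calving) or to a Control group, and samples were taken at weeks -3, 2 and 6 relative to calving. The fitted arrays were 8, 7 and 8 Control arrays and 6, 8 and 8 SARA arrays at weeks -3, 2 and 6, 45 in all. A further 9 arrays carry the word Non in place of a group in the labels. Its meaning was not settled, and these arrays entered no comparison between SARA and Control. Per the labels' protocols the RNA came from rumen epithelium, whereas the tissue label says liver. The 14 measured hepatocyte markers fixed in advance had a median level at percentile 99.6 of all genes tested.

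The deposited scanner values are intensity values on a linear scale, from Agilent Feature Extraction per the file headers, and the processed signal used here was already background-subtracted by that software. The file headers name version 11.0.1.1 and the submitters' processing notes name version 9.5. The series' value table holds log2 values that the authors deposited for the same arrays, with the method of scaling unstated. Set against the scanner values of each array, its columns gave slopes of 0.987 to 1 and Pearson correlations of 0.999 to 1 across 15068 probes. Their 75th percentile was 0 and their medians lay between -3.16 and -1.13, or -3.16 and -2.76 over the fitted arrays. Any baseline shift of single genes before deposit stays unknown, and 0 columns lacked a sample. The table served as an alternative.

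Control spots were left out, and 583 spots marked as outliers on the fitted arrays were set to missing. Log2 processed signals had each array's 75th percentile subtracted, and spots of 1 probe were averaged. The array holds 15008 other probes, 14952 gene names and 44 names with several probes. Accessions on the array gave a current symbol for 11616 probes, which differed from the name in the files for 741, and 683 names were updated. By name, 13658 probes matched a listed gene through the symbol, 37 through a synonym and 695 through the accession alone, and 618 kept the name in the files unmatched. A probe was kept if it was well above background on at least 6 fitted arrays, which left 11939 probes and 11901 genes, 11480 of them with a symbol. Of the several kept probes of a gene, the brightest on average stood for it. For 17 of the 27 such genes the lowest correlation between probes across arrays was under 0.5. Between 8349 and 12221 probes were well above background per fitted array, and the number of arrays limits the precision. No 2 arrays were close enough to be 1 library. The most alike, Control No. 5 at weeks 2 and 6, correlated at 0.991 across genes and come from 1 cow. Positions are those of the array files, on cattle build bosTau6 per the file headers. Where a probe lies within a gene's exons or untranslated regions was not analysed here, and no genome sequence was used.

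All 45 arrays entered 1 model with 6 group means (limma 3.58.1 with lmFit and eBayes, R 4.3.3). Adjusted p-values follow Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 passed. SARA was compared with Control at each week and over the average of the weeks, where the cow was a random block through duplicateCorrelation (statmod 1.5.0). Weeks were compared within each group, and the difference of these changes between groups was tested as an interaction. A fold change is the difference of mean log2 signals. A gene that was not well above background on any array of a group has only a bound there, given as at least N-fold. It sets the brighter group's mean against the mean, per dim array, of the higher of the probe's own signal and the lowest signal of any probe well above background.

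Gene groups were tested as 35 lists, of pathways and of markers of cell types that a liver sample could hold. Each was tested with limma's cameraPR at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way. Members past the threshold were also counted after adjustment over the list alone. The design, these lists, a first set of alternative settings and the rule for naming genes were fixed before the data were examined. In each comparison the rule took, of the genes with a symbol that passed, the 8 of largest increase, the 8 of largest decrease and up to 3 members of each list by smallest p. Where fewer than 10 passed, it added those of smallest unadjusted p up to 10. It always took PC, PCK1, CPT1A, FGF21, IGF1, HP, LBP and CYP7A1. The key gene SAA3 was also named by the rule and was not among the genes tested. Some items that the rule named are not reported here, other named genes are left out for room, and genes named outside the rule are said to be so.

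The cattle numbers of the labels mark 1 cow within a group. Residuals of 42 array pairs of 1 cow correlated across genes with a median of 0.393, over 0.1 in 39 pairs, with a lowest value of 0.0244. Other pairs had a median of -0.0732, or 0.182 within 1 set of slides. The same number in SARA and Control marks different cows, and 21 such pairs had a median of 0.0991, over 0.1 in 10. Arrays lay on 7 slides scanned on 4 days. Slides 1 to 4 form scan set 1, with 30 arrays and several weeks on each slide, and slides 5 to 7 form scan set 2, with 24 arrays and a single week on each slide. Week and slide are partly confounded in scan set 1 as well, where SARA arrays of weeks -3 and 6 shared no slide. Every cow lay in 1 scan set. The first set of alternatives held normexp background correction with an offset of 50, quantile normalization, no filter, a filter on all arrays, the mean over probes, fewer or more groups in the fit, slide, cow or cattle number as a block, a trended and robust variance, and the series' value table. Added after seeing the data were fits without the library labelled Control week 2 No. 2, without 4 libraries that stood apart, with scan set as a block, and within each scan set, and, for the lists alone, fits without each library in turn and without SARA week 6 Nos. 4 and 8.

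The tests were tried on simulated arrays with 200 changed genes among 11901. These had each gene's mean and residual spread, a within-cow correlation of 0.2 and no slide or scan set effect. Of genes changed 2-fold, 52.2%, 44.8% and 59.7% were recovered between SARA and Control at weeks -3, 2 and 6, and 74.6% in the average over weeks. Of 4-fold changes 83.3%, 87.9%, 93.9% and 100% were recovered. Within Control, 56.7%, 55.2% and 55.2% of 2-fold changes were recovered from weeks -3 to 2, -3 to 6 and 2 to 6, and within SARA 34.3%, 53.7% and 58.2%. For the difference of changes the shares were 19.4%, 26.9% and 22.4%. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.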

Results

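Liver gene expression was measured in 8 Control and 8 SARA cows at weeks -3, 2 and 6 relative to calving, with up to 3 arrays per cow. Per the labels, the SARA cows were those whose rumen pH stayed low for hours a day soon after calving, so the comparisons ask how the liver of cows with and without SARA differed and how it changed over time. Values are log2 signal relative to each array's 75th percentile. A change is the later week minus the earlier 1, or SARA minus Control, and each is followed by its standard error (SE). No. stands for the cattle number within a group. The 14 measured hepatocyte markers had a mean level of 6.58 over the fitted arrays. The library labelled Control week 2 No. 2 stood apart. Its hepatocyte marker mean was -1.94, against 6.48 on the next lowest Control array of week 2, and its median correlation with the other arrays was 0.742, where the next lowest array had 0.931. Values without it were computed after seeing the data and are given for some results. In 2 SARA libraries of week -3, Nos. 3 and 4, the skeletal muscle marker means were 0.17 and -0.61, against a median of -5.29 on the other SARA arrays of that week. Scan set 1 (slides 1 to 4) and scan set 2 (slides 5 to 7) are compared as batches. The plot of marker means shows the markers of hepatocytes and skeletal muscle on every array.

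**Figure D1:**
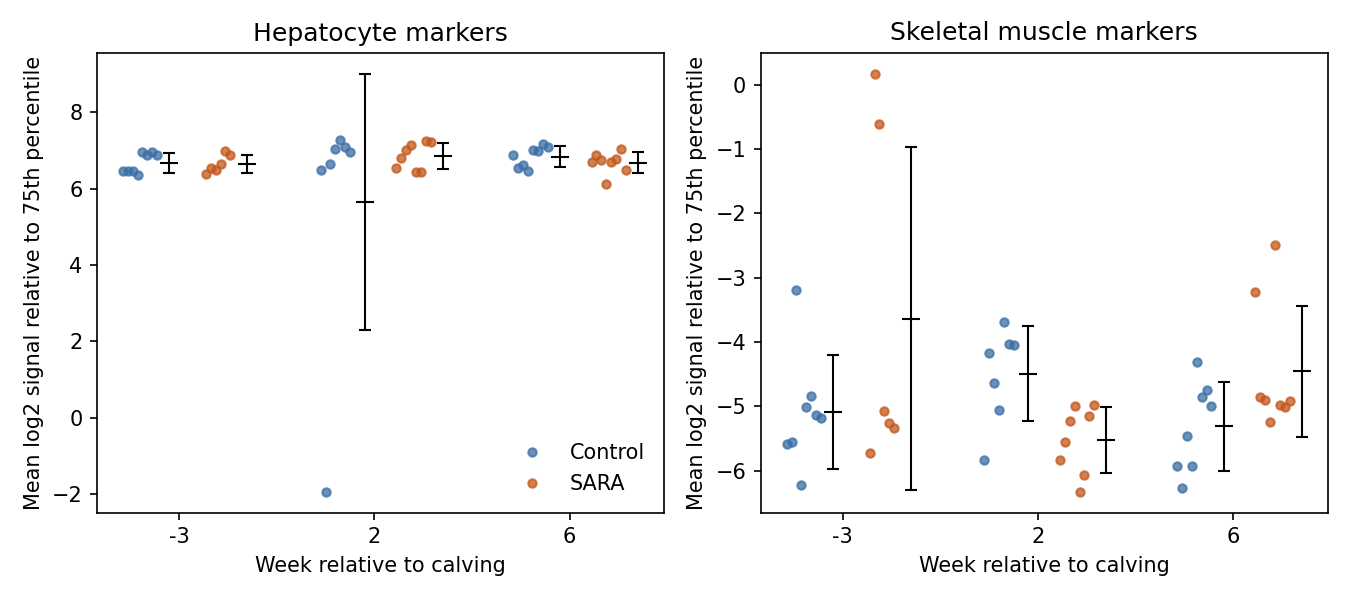
Mean log2 signal, relative to each array's 75th percentile, of the hepatocyte markers and the skeletal muscle markers, per array (points) by week and group, with the group mean and SD (bar). Control week 2 No. 2 lies at -1.94 for hepatocyte markers. SARA week -3 Nos. 3 and 4 lie at 0.17 and -0.61 for muscle markers.

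From week -3 to week 2, several cell division transcripts were higher in Control arrays, No. 2 of week 2 included, and those of IGF1, IGFALS, SFTPD and CGN1 were lower. Among the division genes, CDKN3, a phosphatase that acts on cyclin-dependent kinases, rose by 3.23 (SE 0.61, n = 7 and 8, adjusted p = 0.0049). CDCA3, which takes part in entry into mitosis, rose by 1.99 (SE 0.36, adjusted p = 0.0033), and the mitotic kinase PBK rose by 2.98 (SE 0.67, adjusted p = 0.020). IGF1, the growth factor that liver secretes under growth hormone, fell by 1.83 (SE 0.36, adjusted p = 0.0058), and IGFALS, which holds it in serum complexes, fell by 2.24 (SE 0.43, adjusted p = 0.0049). The collectin SFTPD, a lectin that binds microbes, fell by 2.55 (SE 0.48, adjusted p = 0.0049), and conglutinin, CGN1, fell by 3.66 (SE 0.81, adjusted p = 0.019). PPARGC1A, a coactivator of gluconeogenic and oxidative genes, rose by 0.98 (SE 0.18, adjusted p = 0.0033).

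In this comparison 102 genes passed with No. 2 of week 2 counted, 64 higher and 38 lower at week 2. Without it 63 of these passed, and the sizes below count it unless stated. The largest increases included CGREF1, a secreted calcium-binding protein (3.75, SE 0.61, adjusted p = 0.0016), and CDC42EP5, which binds the small GTPase CDC42 (2.43, SE 0.38, adjusted p = 0.0012). Counting No. 2, both rose in 7 of 7 cows with both weeks and IGF1 fell in 7 of 7. CDKN3 and CDCA3 rose in 6 of 7. RIMKLA was not well above background on any week -3 array and at least 2.69-fold higher at week 2, where 5 of 7 arrays measured it (adjusted p = 0.0025). ALOX15, a lipoxygenase, was not well above background at week 2 and at least 2.74-fold lower there (adjusted p = 0.0077). ASB15, at least 1.30-fold lower by the same rule, turned to 0.058 under normexp background correction. The probes of the genes with the most values here lie at chromosome 11, 72524627 to 72524686 (CGREF1), chromosome 18, 63119876 to 63119935 (CDC42EP5), chromosome 5, 66532901 to 66532960 (IGF1), chromosome 28, 35824485 to 35824544 (SFTPD) and 35602603 to 35602662 (CGN1), and chromosome 6, 44854820 to 44854879 (PPARGC1A). Of the other key genes fixed in advance, PC, the anaplerotic enzyme of gluconeogenesis, had 0.40 (SE 0.44, adjusted p = 0.741) and, without the library Control week 2 No. 2, 1.17 (adjusted p = 0.00088). With that library and without it, PCK1 had 0.17 and 0.72, CPT1A 0.47 and 0.56, FGF21 1.20 and 1.95, HP -1.78 and -0.57, LBP -1.32 and -0.29, and CYP7A1 -0.86 and 0.16, and none of these passed in either case.

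By gene list, 8 of the 33 measured cell cycle genes rose and 0 fell in Control from week -3 to week 2, and 22 rose when adjusted over the list alone. The list's median change was 1.36, with an adjusted p = 0.046 with an estimated correlation and 0.0094 by fry. Of the 25 glycolysis genes TPI1, triosephosphate isomerase, rose by 0.61 (SE 0.16) and PKLR, the liver pyruvate kinase, fell by 0.91 (SE 0.24). The list's median was 0.18, 3 rose and 1 fell when adjusted over the list alone, and its adjusted p = 0.046 with an estimated correlation. Of the 23 genes of the growth hormone and insulin axis IGF1 and IGFALS fell and 0 rose, against 5 that fell and 1 that rose when adjusted over the list alone. Its median was -0.21 and its adjusted p = 0.046 with an estimated correlation. Camera's preset test called 13 lists here and only these 3 held with an estimated correlation. When each library was left out in turn, chosen after seeing the data, that call held in 4 of 15 fits for the cell cycle, 5 of 15 for glycolysis and 4 of 15 for the growth hormone and insulin axis, with adjusted p up to 0.125, 0.0781 and 0.275. The median of the growth hormone and insulin axis was -0.070 without Control week 2 No. 7. The lists of acute phase proteins (median -1.19), complement (-1.0), bile acid synthesis (-0.80), xenobiotic metabolism (-0.78) and urea cycle (-0.71) were lower, beside hepatocyte markers (-1.09), macrophage markers (-0.58) and endothelium markers (-0.29). With an estimated correlation their adjusted p ran from 0.472 (complement) through 0.475 (acute phase proteins) to 0.647 (hepatocyte). The medians of these lists without Control week 2 No. 2 were acute phase proteins -0.10, complement -0.23, bile acid synthesis -0.069, xenobiotic metabolism -0.15, urea cycle -0.046, hepatocyte markers 0.074, macrophage markers -0.15 and endothelium markers -0.10. The unfolded protein response (0.27, adjusted p = 0.475 with an estimated correlation) and oxidative phosphorylation (0.060, adjusted p = 0.828 with an estimated correlation, 0.039 without Control week -3 No. 4) were higher. Within scan set 1, within scan set 2 and with slide as a block, in this order, the medians were acute phase proteins -2.68, -0.15 and -1.11, complement -2.11, -0.22 and -1.03, bile acid synthesis -1.98, -0.058 and -1.10, xenobiotic metabolism -1.73, -0.072 and -0.88, urea cycle -1.69, 0.022 and -0.95, hepatocyte markers -2.64, 0.17 and -1.30, macrophage markers -0.96, -0.31 and -0.83, endothelium markers -0.54, -0.046 and -0.27, the unfolded protein response -0.030, 0.43 and 0.17, and oxidative phosphorylation 0.049, 0.14 and 0.12.

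The library Control week 2 No. 2 lies in scan set 1. Leaving it out gave 107 genes, 63 of them among the 102. It took the adjusted p of PKLR to 0.126, RRM2, a ribonucleotide reductase subunit, from 0.049 to 0.128, and KIF20A, a mitotic kinesin, from 0.022 to 0.060. IGF1 then had -1.33 (adjusted p = 0.0058), CGN1 -2.43 (0.014) and CDKN3 an adjusted p = 0.011. The cell cycle list then had a median of 1.03, with 2 that rose, 20 when adjusted over the list alone, and an adjusted p = 0.108 with an estimated correlation. The growth hormone and insulin axis had an adjusted p = 0.275 with an estimated correlation and glycolysis 0.039. Lipoprotein assembly then had 0.28 with 4 members that rose (adjusted p = 0.039 with an estimated correlation). With the cow as a fixed block as well, neither list passed with an estimated correlation (0.148 for glycolysis and, at a median of 0.20, 0.065 for lipoprotein assembly). With the cow as a block 225 genes passed, 97 of them among the 102, RRM2 had an adjusted p = 0.069, and the cell cycle list had a median of 1.36 and an adjusted p = 0.404 with an estimated correlation, as had the growth hormone and insulin axis. With slide as a block 11 passed, 7 of them among the 102, with CGREF1 (adjusted p = 0.023), CDC42EP5 (0.033) and IGF1 (0.029) among them and CDKN3 (0.304) and PPARGC1A (0.081) not. Within scan sets 1 and 2, CGREF1 had 5.52 and 2.34, CDC42EP5 2.86 and 2.02, IGF1 -2.60 and -1.28, SFTPD -2.41 and -2.74, CDKN3 3.71 and 2.88 and PPARGC1A 0.89 and 1.07. The cell cycle list had 1.59 and 1.06 within them and 1.22 with slide as a block, glycolysis 0.16, 0.26 and 0.25, and the growth hormone and insulin axis -0.41, -0.17 and -0.23. The plot of 6 genes by week shows the arrays behind some of these values.

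**Figure D2:**
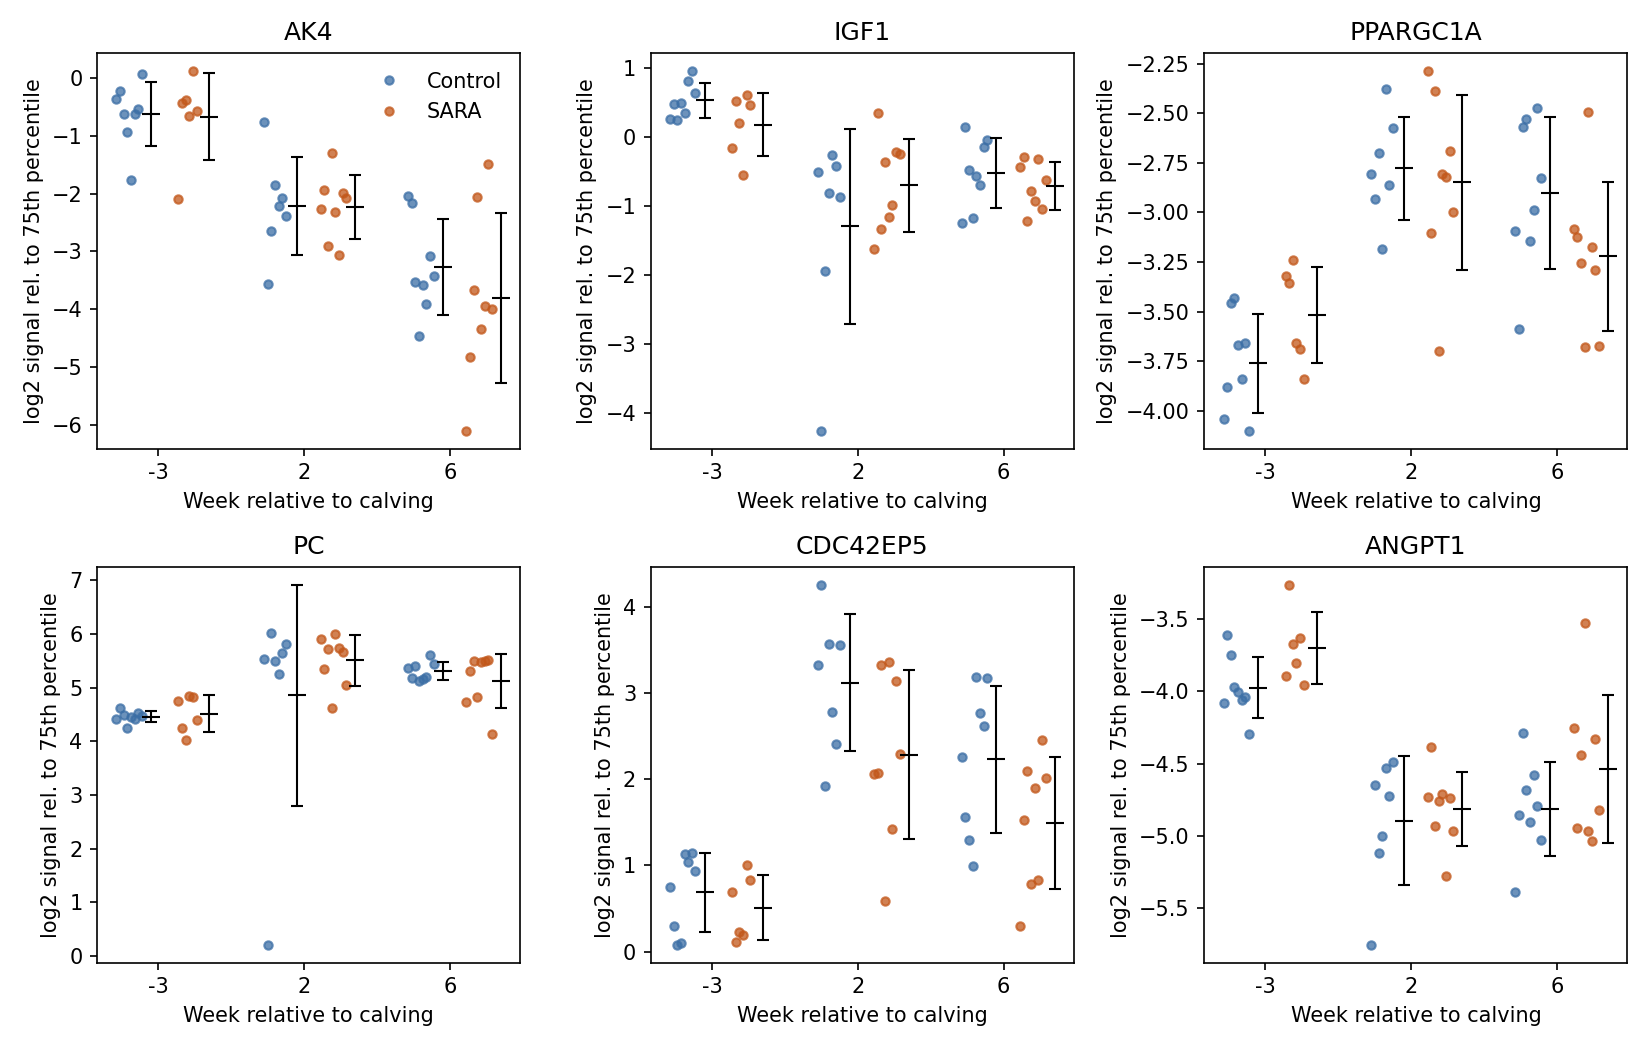
Log2 signal, relative to each array's 75th percentile, of AK4, IGF1, PPARGC1A, PC, CDC42EP5 and ANGPT1 per array (points) at weeks -3, 2 and 6 in Control and SARA cows, with mean and SD (bar). AK4 is lower at week 6 than at week -3 in both groups, by 2.64 in Control and 3.13 in SARA.

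From week -3 to week 6, 12 genes passed in Control, 6 higher and 6 lower, each in that direction in 8 of 8 cows. AK4, a mitochondrial adenylate kinase, fell by 2.64 (SE 0.44, n = 8 and 8, adjusted p = 0.0032), and A2M, a protease inhibitor of plasma, fell by 1.88 (SE 0.39, adjusted p = 0.026). The liver transcription factor FOXA3 fell by 1.90 (SE 0.39), the collectin CL46 fell by 1.58 (SE 0.34), SKIL, a repressor of SMAD signalling, fell by 0.96 (SE 0.19) and the vessel growth factor ANGPT1 fell by 0.84 (SE 0.18). PMM2, a phosphomannomutase of glycoprotein assembly, rose by 0.64 (SE 0.11, adjusted p = 0.0032), ATAD3A, an ATPase of mitochondrial membranes, rose by 0.90 (SE 0.15, adjusted p = 0.0032), and PPARGC1A rose by 0.86 (SE 0.17, adjusted p = 0.025). PRAP1 (2.35, SE 0.51), the small GTPase DIRAS3 (2.15, SE 0.41) and the potassium channel KCNK5 (1.35, SE 0.30) rose too. The probes of AK4 and ANGPT1 lie at chromosome 3, 80491346 to 80491405, and chromosome 14, 59423493 to 59423552.

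Of the 25 glycolysis genes 0 passed over all genes tested in Control from week -3 to week 6 and 1 rose when adjusted over the list alone, with a list median of 0.16 and an adjusted p = 0.0013 with an estimated correlation (0.120 by fry). The call held in 16 of 16 fits that left out 1 library, at medians of 0.10 to 0.21. Camera's preset test called 11 lists, and this was the only 1 of them that held. Gluconeogenesis and propionate use had 0.30 (adjusted p = 0.387 with an estimated correlation), cholesterol synthesis 0.35 (0.690), mitochondrial fatty acid oxidation, in which PPARGC1A rose, 0.21 (0.690), peroxisomal oxidation 0.24 (0.690), triglyceride synthesis 0.17 (0.690), oxidative phosphorylation 0.13 (0.391) and urea cycle 0.19 (0.905). Extracellular matrix had -0.26 (0.690), T and NK cell markers -0.32 (0.690) and macrophage markers -0.32 (0.849). Single libraries moved gluconeogenesis to 0.19 and triglyceride synthesis to 0.11 (Control week -3 No. 2 left out), macrophage markers to -0.12 (Control week 6 No. 4) and T and NK cell markers to -0.21 (Control week -3 No. 6). In scan set 1, in scan set 2 and with slide as a block these lists had gluconeogenesis 0.37, 0.29 and 0.74, cholesterol synthesis 0.36, 0.30 and 0.52, mitochondrial fatty acid oxidation 0.19, 0.20 and 0.55, peroxisomal oxidation 0.33, 0.21 and 0.58, triglyceride synthesis 0.19, 0.22 and 0.44, oxidative phosphorylation 0.090, 0.17 and 0.28, urea cycle 0.19, 0.20 and 0.77, extracellular matrix -0.29, -0.21 and -0.65, T and NK cell markers -0.43, -0.37 and -0.78, and macrophage markers -0.18, -0.34 and 0.065. Of the key genes, PC had 0.85 (adjusted p = 0.853), PCK1, which forms phosphoenolpyruvate, 1.09 (0.516) and IGF1 -1.05 (0.443). Without Control week 2 No. 2, which adds to the shared spread alone in this comparison, 42 genes passed, PC had an adjusted p = 0.0097, IGF1 0.032 and PCK1 0.063. Gluconeogenesis then had an adjusted p = 0.031 with an estimated correlation, with 1 member that rose and 5 when adjusted over the list alone. With the cow as a fixed block as well, gluconeogenesis had 0.044 and glycolysis 0.057. With the cow as a block 37 genes passed, all 12 among them. With slide as a block 2 passed, ATAD3A (1.44, adjusted p = 0.012) among them and AK4 (0.281) not. AK4 had -2.51 and -2.78 within scan sets 1 and 2, and the glycolysis list had 0.071 and 0.17, and 0.11 with slide as a block.

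From week 2 to week 6 the cell cycle list ran the other way in Control, with a median of -1.43. 0 of its 33 members passed over all genes tested and 26 fell when adjusted over the list alone, with an adjusted p = 0.062 with an estimated correlation and 0.0025 by fry. The nearest genes were PBK (-3.28, SE 0.67, adjusted p = 0.083), KIF20A (-2.21) and BIRC5, a regulator of chromosome segregation (-2.09, adjusted p = 0.091). In all 0 genes passed by limma and 1555 had an unadjusted p under 0.05. Other settings gave 0 to 489 genes, 489 with slide as a block and 3 there without Control week 2 No. 2. Without that library the list had -1.13 and an adjusted p = 0.030 with an estimated correlation, with 24 that fell when adjusted over the list alone, and 1 gene passed. With the cow as a block it had -1.39 and an adjusted p = 0.551 with an estimated correlation, and without that library as well -1.02 and 0.382. It had -1.93 and -0.79 within scan sets 1 and 2 and -2.21 with slide as a block. Lists called higher by the preset test alone were hepatocyte markers (1.32, adjusted p = 0.531 with an estimated correlation), urea cycle (1.13, 0.456, 16 that rose when adjusted over the list alone), acute phase proteins (1.1, 0.531), complement (1.05, 0.469), bile acid synthesis (1.04, 0.456), xenobiotic metabolism (0.95, 0.456), peroxisomal oxidation (0.44, 0.481), cholesterol synthesis (0.40, 0.562), gluconeogenesis (0.39, 0.481), mitochondrial fatty acid oxidation (0.35, 0.531), endothelium markers (0.28, 0.531) and lipoprotein assembly (0.26, 0.573). T and NK cell markers had -0.40 (0.573) and extracellular matrix -0.37 (0.573). With the library Control week 2 No. 2 left out, the medians of these lists were hepatocyte markers 0.055, urea cycle 0.32, acute phase proteins -0.032, complement 0.096, bile acid synthesis 0.19, xenobiotic metabolism 0.25, peroxisomal oxidation 0.044, cholesterol synthesis -0.041, gluconeogenesis 0.047, mitochondrial fatty acid oxidation -0.0057, endothelium markers 0.030, lipoprotein assembly -0.16, T and NK cell markers -0.22 and extracellular matrix -0.058. Without Control week 6 No. 4 alone T and NK cell markers had -0.21, and without other single libraries lipoprotein assembly lay between 0.17 and 0.52. Medians by scan set 1, scan set 2 and slide block were hepatocyte markers 2.92, 0.013 and 2.31, urea cycle 2.39, 0.19 and 1.91, acute phase proteins 2.79, -0.039 and 1.99, complement 2.31, 0.092 and 1.84, bile acid synthesis 2.12, 0.048 and 1.55, xenobiotic metabolism 1.83, 0.14 and 1.53, peroxisomal oxidation 1.12, 0.020 and 0.84, cholesterol synthesis 0.70, 0.19 and 0.64, gluconeogenesis 0.83, 0.012 and 0.70, mitochondrial fatty acid oxidation 0.97, 0.072 and 0.78, endothelium markers 0.52, 0.075 and 0.35, lipoprotein assembly 1.06, -0.019 and 0.88, T and NK cell markers -0.55, -0.084 and -0.62, and extracellular matrix -0.67, -0.11 and -0.63. The plot of the cell cycle list joins the arrays of each cow.

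**Figure D3:**
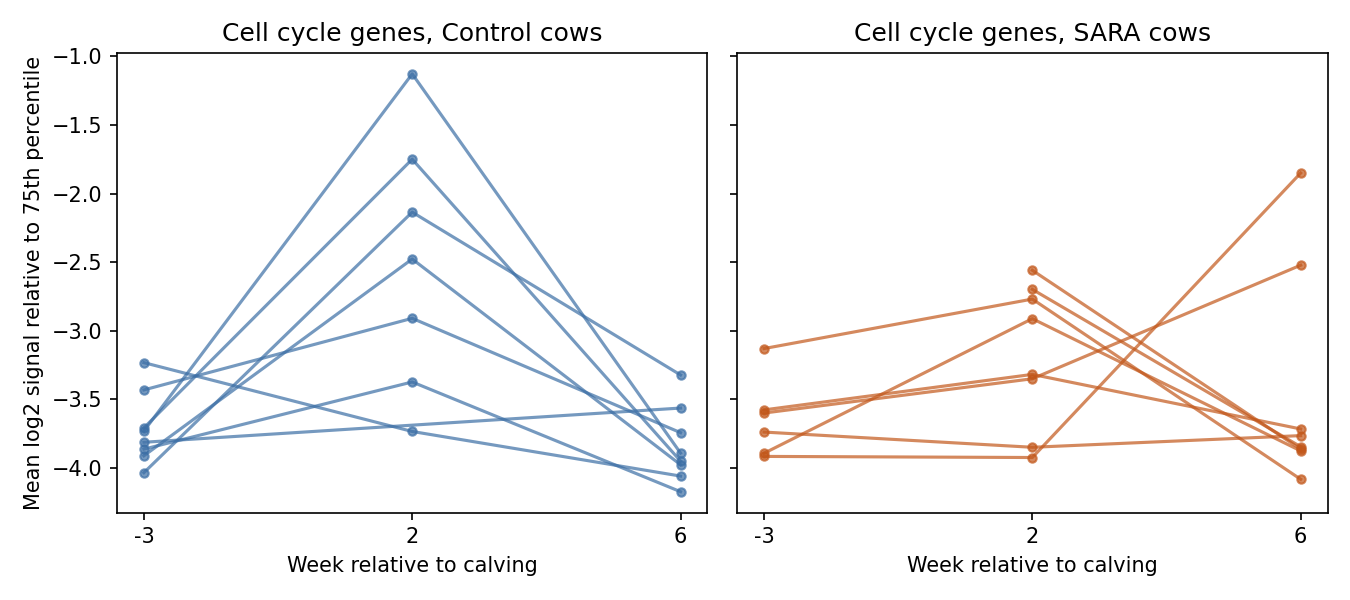
Mean log2 signal, relative to each array's 75th percentile, of the 33 cell cycle genes per array at weeks -3, 2 and 6. Each line joins the arrays of 1 cow, Control on the left and SARA on the right. The mean was higher at week 2 than at week -3 in 10 of 13 cows.

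In SARA cows, TGFB2, a growth factor of tissue repair, rose by 1.43 (SE 0.27, n = 8 and 6, adjusted p = 0.022) from week -3 to week 2, in 5 of 6 cows, and ANGPT1 fell by 1.11 (SE 0.19, adjusted p = 0.012), in 6 of 6. ANGPT1 had 0.17 under normexp background correction. From week -3 to week 6, AK4 fell by 3.13 (SE 0.47, adjusted p = 0.00059) in 6 of 6 cows, GDF15, a secreted stress cytokine, fell by 2.61 (SE 0.52, adjusted p = 0.037) in 5 of 6, and TGFB2 rose by 1.43 (SE 0.27, adjusted p = 0.023) in 6 of 6. Both comparisons share the week -3 arrays. The probes of TGFB2 and GDF15 lie at chromosome 16, 22587569 to 22587628, and chromosome 7, 4711422 to 4711481. These were the only genes that passed, 2 from week -3 to week 2 and 3 from week -3 to week 6, and 667 and 449 genes had an unadjusted p under 0.05. Those nearest below the threshold were the mitochondrial protein CISD1 (adjusted p = 0.068; not well above background on any week -3 array and at least 1.60-fold higher at week 2, where 3 arrays measured it), PDLIM2 (-0.86, 0.084) and CDC42EP5 (1.78, 0.112) at week 2. PC had 0.99 (adjusted p = 0.836) and CPT1A, which admits fatty acids to mitochondria, 0.78 (0.373) at week 2. From week 2 to week 6, 0 genes passed by limma, 504 had an unadjusted p under 0.05, and other settings gave 0 to 66, with RASAL3, a regulator of Ras in blood cells, nearest (1.76, SE 0.34, adjusted p = 0.089, higher in 8 of 8 cows).

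By list, camera's preset test called 9, 2 and 10 lists over the 3 intervals in SARA and 0 of them held with an estimated correlation. Skeletal muscle markers had -1.88 from week -3 to week 2, with 6 of 12 that fell when adjusted over the list alone (adjusted p = 0.068 with an estimated correlation), -0.94 to week 6 (0.948) and 0.92 from week 2 to week 6 (0.690). Without SARA week -3 Nos. 3 and 4, SARA week 6 No. 8 and Control week 2 No. 2 the values were -0.28, 0.45 and 0.81. Leaving out SARA week -3 No. 3 alone gave -1.07 to week 2 and -0.073 to week 6. In scan set 1, in scan set 2 and with slide as a block the muscle list had -3.08, 0.33 and -2.52 over the first interval, -1.63, 0.32 and -1.18 over the second and 1.05, -0.0078 and 0.87 over the last. From week -3 to week 2 the cell cycle list had 0.53 and peroxisomal oxidation 0.22. Mitochondrial fatty acid oxidation had 0.20, triglyceride synthesis 0.18 and oxidative phosphorylation 0.12. Each adjusted p was 0.834 with an estimated correlation. Lower were T and NK cell markers (-0.43, 0.798), stellate cell markers (-0.32, 0.705) and extracellular matrix (-0.27, 0.798). The 3 batch values, in the same order, were the cell cycle 0.54, -0.13 and 0.53, peroxisomal oxidation 0.21, 0.22 and 0.41, mitochondrial fatty acid oxidation 0.25, 0.22 and 0.34, triglyceride synthesis 0.19, 0.093 and 0.31, oxidative phosphorylation 0.072, 0.22 and 0.19, T and NK cell markers -0.52, -0.31 and -0.48, stellate cell markers -0.43, -0.27 and -0.42, and extracellular matrix -0.30, -0.41 and -0.42. The interferon response had 0.36 from week -3 to week 6 (0.948) and 0.31 from week 2 to week 6 (0.690), and 0.14 and -0.030 when SARA week 6 No. 5 was left out. On that array the list's mean was 0.65, against -2.25 to -1.51 on the other SARA arrays of week 6. From week 2 to week 6 T and NK cell markers had 0.42 (0.690), inflammatory signalling 0.15 (0.631) and extracellular matrix 0.16 (0.858), and cholesterol synthesis -0.27 (0.858), peroxisomal oxidation -0.27 (0.858), triglyceride synthesis -0.24 (0.690), mitochondrial fatty acid oxidation -0.17 (0.858) and lipoprotein assembly -0.25 (0.858). Leaving out SARA week 6 Nos. 4 and 8 gave T and NK cell markers -0.063, inflammatory signalling 0.11, extracellular matrix 0.040, cholesterol synthesis -0.097, peroxisomal oxidation -0.078, triglyceride synthesis -0.080, mitochondrial fatty acid oxidation -0.0021 and lipoprotein assembly -0.31, and none of these was then called by the preset test. Without No. 8 alone T and NK cell markers had 0.092. Their batch values from week 2 to week 6 were the interferon response 0.38, 0.085 and 0.46, T and NK cell markers 0.21, 0.93 and 0.24, inflammatory signalling 0.064, 0.27 and 0.17, extracellular matrix 0.088, 0.26 and 0.077, cholesterol synthesis -0.19, -0.58 and -0.089, peroxisomal oxidation -0.19, -0.43 and 0.11, triglyceride synthesis -0.22, -0.31 and -0.037, mitochondrial fatty acid oxidation -0.12, -0.33 and 0.0097, and lipoprotein assembly -0.24, -0.39 and 0.014, and those of the interferon response from week -3 to week 6 were 0.51, 0.17 and 0.55. Without Control week 2 No. 2 lipoprotein assembly had an adjusted p = 0.026 with an estimated correlation, with 6 that fell when adjusted over the list alone, and 0.0060 with the cow as a fixed block as well.

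Without that library, which is no SARA array and enters through the shared spread, 27, 3 and 1 genes passed in SARA over the 3 intervals. CISD1 then had an adjusted p = 0.020, PDLIM2 0.0241, CDC42EP5 0.0272, PC at week 2 0.014 and RASAL3 0.036. With the cow as a block 32, 1 and 3 genes passed. TGFB2 had an adjusted p = 0.0504 at week 2 and 0.127 at week 6, GDF15 0.0635, ANGPT1 0.0038, AK4 0.00057, CISD1 0.0020, PDLIM2 0.0474, CDC42EP5 0.012, CPT1A 0.0474 and RASAL3 0.026. With slide as a block 0 genes passed, with adjusted p = 0.356 for TGFB2 and 0.231 for ANGPT1 at week 2 and 0.164 for AK4. Within scan sets 1 and 2, TGFB2 had 1.42 and 1.49 and ANGPT1 -1.14 and -1.06 at week 2, and AK4 had -3.26 and -2.51 and GDF15 -2.53 and -2.48 at week 6.

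Between SARA and Control cows, 0 genes passed by limma at week -3, at week 2, at week 6 or averaged over the weeks, and 130, 1352, 677 and 607 genes had an unadjusted p under 0.05. The smallest adjusted p were 1.00, 0.201, 0.0632 and 0.891. Normexp, quantile normalization and slide as a block gave 0 in each as well, and within scan set 2, with 4 Control and 2 SARA arrays a week, 0, 3, 548 and 0 genes passed. For the median gene, the 95% interval reached 0.557, 0.533, 0.515 and 0.386 on either side of the estimate. At week -3 the skeletal muscle markers were higher in SARA by the list test (median 1.60, 0 of 12 passed, adjusted p = 0.033 with an estimated correlation and 0.994 by fry). That call held in 9 of 14 fits that left out 1 library, and the median was 0.76 without SARA week -3 No. 3 alone (adjusted p = 0.977) and 0.91 without No. 4 alone (0.624). Their values were 2.76 and -0.22 within scan sets 1 and 2, 1.01 with slide as a block and -0.26 without SARA week -3 Nos. 3 and 4, Control week 2 No. 2 and SARA week 6 No. 8. Without Control week 2 No. 2 alone the list's adjusted p = 0.071 with an estimated correlation. Endothelium markers had -0.19 (adjusted p = 0.987 with an estimated correlation), or -0.11 without SARA week -3 No. 3. GADD45G had -0.99 there, and PLAGL2 and DTX1, also near the smallest p, were not well above background on any SARA array of that week.

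At week 2 the genes of smallest p between SARA and Control were RARS2, a mitochondrial arginyl-tRNA synthetase (0.66, SE 0.14, n = 8 and 7, adjusted p = 0.201), and JPH1, a junction protein of muscle membranes (-1.98, adjusted p = 0.201, -2.91 and -0.56 within scan sets 1 and 2). The galectin LGALS3 had -2.52 (adjusted p = 0.422) with Control week 2 No. 2 counted. Of the acute phase genes LBP had 1.68 (0.422), or 0.65 without Control week 2 No. 2, and HP, haptoglobin, 1.57 (0.612), or 0.36 without it. The preset test called 16 lists at week 2, 10 without that library, and 0 held with an estimated correlation, where adjusted p ran from 0.328 to 0.692. Higher in SARA were acute phase proteins (1.41), hepatocyte markers (1.22), complement (1.09, 8 of 20 when adjusted over the list alone), bile acid synthesis (1.03), urea cycle (0.98), xenobiotic metabolism (0.76), peroxisomal oxidation (0.49), lipoprotein assembly (0.49), mitochondrial fatty acid oxidation (0.34), cholesterol synthesis (0.25) and the growth hormone and insulin axis (0.23). Lower were skeletal muscle markers (-1.10), the cell cycle (-0.64), T and NK cell markers (-0.56), extracellular matrix (-0.47) and the unfolded protein response (-0.23). The medians at week 2 without Control week 2 No. 2 were acute phase proteins 0.20, hepatocyte markers -0.050, complement 0.22, bile acid synthesis 0.10, urea cycle 0.20, xenobiotic metabolism 0.025, peroxisomal oxidation 0.036, lipoprotein assembly -0.11, mitochondrial fatty acid oxidation 0.0084, cholesterol synthesis -0.092, the growth hormone and insulin axis 0.16, skeletal muscle markers -0.95, the cell cycle -0.42, T and NK cell markers -0.52, extracellular matrix -0.25 and the unfolded protein response -0.19, and 0 complement genes then passed when adjusted over the list alone. Leaving out Control week 2 No. 1 instead gave the growth hormone and insulin axis 0.076. In scan set 1, in scan set 2 and with slide as a block the week 2 medians were acute phase proteins 3.30, 0.12 and 1.69, hepatocyte markers 2.81, 0.19 and 1.56, complement 2.15, 0.14 and 1.25, bile acid synthesis 2.19, 0.073 and 1.12, urea cycle 2.23, 0.086 and 1.22, xenobiotic metabolism 1.67, 0.13 and 1.00, peroxisomal oxidation 0.98, 0.074 and 0.55, lipoprotein assembly 1.64, 0.082 and 0.75, mitochondrial fatty acid oxidation 0.80, -0.041 and 0.30, cholesterol synthesis 0.54, -0.079 and 0.31, the growth hormone and insulin axis 0.34, 0.20 and 0.24, skeletal muscle markers -0.57, -0.61 and -0.73, the cell cycle -0.88, -0.93 and -0.89, T and NK cell markers -0.66, 0.0092 and -0.39, extracellular matrix -0.76, -0.16 and -0.53, and the unfolded protein response -0.29, -0.15 and -0.28.

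At week 6 the smallest p between SARA and Control was that of NR2C2, a nuclear receptor (0.70, SE 0.13, n = 8 and 8, adjusted p = 0.0632). It had 0.53 and 1.01 within scan sets 1 and 2, and it passed without Control week 2 No. 2 (adjusted p = 0.039) and not with the cow as a block (0.195). CIDEC, a protein of lipid droplets, had -1.77 (SE 0.47, adjusted p = 0.717, -1.58 and -1.68 within the scan sets). The preset test called 10 lists and 0 held with an estimated correlation, where adjusted p ran from 0.504 to 0.632. Lower in SARA were cholesterol synthesis (-0.41), triglyceride synthesis (-0.29, 1 of 30 when adjusted over the list alone), fatty acid synthesis (-0.26), mitochondrial fatty acid oxidation (-0.24), peroxisomal oxidation (-0.24), gluconeogenesis (-0.22) and oxidative phosphorylation (-0.13), and higher were the cell cycle (0.39), interferon response (0.37) and inflammatory signalling (0.21). The interferon response had 0.10 without SARA week 6 No. 5 and was then not called by the preset test. In 2 SARA libraries of week 6, Nos. 4 and 8, the cell cycle means were -2.52 and -1.85, against -4.08 to -3.72 on the other SARA arrays of that week. Leaving out these 2 gave cholesterol synthesis -0.19, triglyceride synthesis -0.11, fatty acid synthesis -0.20, mitochondrial fatty acid oxidation -0.025, peroxisomal oxidation -0.10, gluconeogenesis -0.022, oxidative phosphorylation 0.036, the cell cycle 0.048, the interferon response 0.43 and inflammatory signalling 0.080. Of the 10 lists only the interferon response was then called by the preset test. By scan set 1, scan set 2 and slide block they were cholesterol synthesis -0.13, -0.91 and -0.39, triglyceride synthesis -0.17, -0.42 and -0.17, fatty acid synthesis -0.089, -0.57 and -0.26, mitochondrial fatty acid oxidation -0.12, -0.38 and -0.17, peroxisomal oxidation -0.27, -0.42 and -0.37, gluconeogenesis -0.22, -0.44 and -0.25, oxidative phosphorylation -0.077, -0.27 and -0.13, the cell cycle 0.26, 0.92 and 0.49, the interferon response 0.46, 0.18 and 0.35, and inflammatory signalling 0.12, 0.21 and 0.23. Averaged over weeks, acute phase proteins (0.45), xenobiotic metabolism (0.25) and urea cycle (0.24) were higher in SARA by the preset test, each with an adjusted p = 0.854 with an estimated correlation. Leaving out Control week 2 No. 2 gave acute phase proteins 0.055, xenobiotic metabolism -0.0018 and urea cycle 0.056. Their batch values, in that order of batches, were acute phase proteins 1.16, -0.075 and 0.63, xenobiotic metabolism 0.52, -0.058 and 0.27, and urea cycle 0.73, -0.084 and 0.34. CYP2B6, a drug-metabolizing cytochrome, had 1.62 (SE 0.43), CIDEC -1.08 (SE 0.32) and FGF21, a hormone of fasting, -1.28 in the average (adjusted p = 0.891, 0.891 and 0.898).

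The change over time was compared between the groups by an interaction. 0 genes passed by limma over any interval, and 214, 106 and 654 genes had an unadjusted p under 0.05 for weeks -3 to 2, -3 to 6 and 2 to 6. Other settings gave 0 but for 1 and 8 genes in the first and last interval within scan set 2 and 1 in the last with Control week 2 No. 2 left out and the cow as a random block. IGF1, which fell in Control by week 2, had a difference of 0.95 (adjusted p = 0.999), or 0.46 without Control week 2 No. 2, and JPH1 had -2.33 (0.999). RASAL3 had 1.98 and the mitotic kinase MELK 2.36 (both 0.742) from week 2 to week 6. Skeletal muscle markers differed by -2.78 from week -3 to week 2 (0 of 12 passed, adjusted p = 0.038 with an estimated correlation, 0.264 by fry). This list had -3.85 and -0.54 within scan sets 1 and 2, -1.70 with slide as a block, -2.90 with the cow as a block (adjusted p = 0.0949 with an estimated correlation), and -0.59 without SARA week -3 Nos. 3 and 4, Control week 2 No. 2 and SARA week 6 No. 8. Its call with an estimated correlation held in 11 of 29 fits that left out 1 library, with an adjusted p up to 0.169. The preset test called 16, 13 and 20 lists over the 3 intervals, and with an estimated correlation only the muscle markers held. In the change to week 6 cholesterol synthesis differed by -0.43 and the interferon response by 0.50 (adjusted p = 0.555 each with an estimated correlation). The latter was 0.23 without SARA week 6 No. 5, and the former -0.22 without SARA week 6 Nos. 4 and 8. From week 2 to week 6 the cell cycle differed by 1.07, T and NK cell markers by 0.76, acute phase proteins by -1.44 and hepatocyte markers by -1.33 (adjusted p from 0.251 to 0.436 with an estimated correlation). Without Control week 2 No. 2 these differences were the cell cycle 0.84, T and NK cell markers 0.63, acute phase proteins -0.16 and hepatocyte markers -0.10. Leaving out SARA week 6 Nos. 4 and 8 instead gave the cell cycle 0.63, T and NK cell markers 0.30, acute phase proteins -1.31 and hepatocyte markers -1.19. Their values in scan set 1, in scan set 2 and with slide as a block were the cell cycle 1.19, 1.85 and 1.42, T and NK cell markers 0.56, 1.12 and 0.82, acute phase proteins -3.06, -0.20 and -1.60, and hepatocyte markers -2.78, -0.45 and -1.62, and for the change to week 6 cholesterol synthesis -0.38, -0.73 and -0.51, and the interferon response 0.54, 0.24 and 0.46.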

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

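Tests chosen only after the result was seen were those of weak hybridisation in the library Control week 2 No. 2, of the shared slide and of the SARA group for the muscle genes, and of 4 of the 5 comparisons of the scan sets (SARA from week -3 to week 2, Control over the same weeks without that library, and Control and SARA from week -3 to week 6). Within each group of 6 to 8 arrays, the highest and the lowest value of each quantity were set against their nearest neighbour, over 138 groups and quantities. Chance picks out about 1 in 20 such groups, or 6.9 here, and 19 values stood far from the rest, 13 of them on the library Control week 2 No. 2.

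The values of Control week 2 No. 2, each with its nearest neighbour of the same group in brackets, were a median correlation with the fitted arrays of 0.742 (0.956) and log2 levels of 0.21 (5.26) for PC, -2.52 (1.03) for PCK1, -4.26 (-1.95) for IGF1, -3.24 (3.16) for LBP and -7.00 (-0.37) for CYP7A1. Its marker means were -1.94 (6.48) for hepatocytes, -2.74 (0.93) for macrophages, -3.28 (-1.96) for neutrophils and -2.88 (-1.65) for endothelium, all lowest, and -0.57 (-2.01) for cholangiocytes, 0.70 (-1.35) for stellate cells and -2.16 (-3.13) for squamous rumen epithelium, all highest. The other 6 values far from their group were PCK1 in Control week -3 No. 2 at -0.78 (0.37), CPT1A in SARA week 6 No. 8 at 0.99 (1.93), T and NK cell markers in Control week 6 No. 4 at -4.06 (-2.99), stellate cell markers in Control week -3 No. 2 at -0.73 (-1.39) and in SARA week 6 No. 4 at -0.70 (-1.48), and skeletal muscle markers in Control week -3 No. 3 at -3.19 (-4.84).

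Control week 2 No. 2 had 9889 probes well above background, against 8349 on the lowest other fitted array, which argues against weak hybridisation. In lists fixed before this test and without the genes already seen, its median level lay above the mean of the other 44 arrays by 5.68 for exocrine pancreas, 4.57 for smooth muscle and 3.47 for intestine, so RNA of another tissue may account for it. Above every other array were 12 of 14 smooth muscle genes (SYNM at 3.75, against -0.92), 7 of 11 intestine genes (LGALS4 at 5.11, against 2.22) and 1 of 13 pancreas genes. The highest pancreas mean was in SARA week -3 No. 7 (2.14, against 0.67 here). Squamous rumen epithelium lay 0.23 above the others, with 2 of 9 above every other array. Which tissue it is stays open, and no biological explanation was tested, since the design gives none for 1 library.

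Skeletal muscle markers were the list whose change from week -3 to week 2 differed between SARA and Control with an estimated correlation, by -2.78, and the SARA libraries of week -3 Nos. 3 and 4 carry it. The other arrays of their slide lay -0.21 from those of the other slides in muscle marker mean, which argues against an effect of the slide, and the other SARA arrays of that week lay -0.15 from the Control arrays, which argues against a difference of the SARA group before calving. Muscle RNA in both samples may be the source: ACTA1, the main actin of skeletal muscle, was at 3.41 and 2.73 in them, against -2.88 on the highest other SARA array of that week, and MYL1 was at 3.45 and 2.24. In another set of muscle genes 57.1% of the 14 measured were higher in both than in every other SARA array of that week, short of the share set in advance for this source and above the share set against it, so muscle RNA cannot be told apart from a rise of some muscle genes alone. TNNI2 (-5.96 and -5.29) and TNNT1 (-6.22 and -6.97) lay near background and decide nothing.

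Many more genes passed over time within scan set 2 than within scan set 1, 1706 against 5 in Control from week -3 to week 2. In scan set 2 each slide holds 1 week, so week and slide are confounded within it. The median residual SD there was 0.428 of that in scan set 1 (0.484 without Control week 2 No. 2). Each group lay on 1 slide there but on several in scan set 1. Lower spread may account for part of the excess but cannot be told apart from slide effects. Of the genes called in scan set 2 from week -3 to week 2, 66.4% in SARA changed in the same direction in scan set 1. In Control 62.8% did, or 70.1% without Control week 2 No. 2. Those that rose had medians of 0.78 in scan set 2 and 0.099 in scan set 1 in SARA. In Control without that library they had 0.53 and 0.12. No spread of such shares was drawn, so they do not decide whether slides are the source. From week -3 to week 6, 46.3% in Control and 49.9% in SARA kept direction, near the share expected of a slide effect. Changes called in scan set 2 alone may thus follow its slides, and a biological change over the same weeks stays open.

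The Non arrays were not part of any comparison between SARA and Control. The 2 of week -3, Nos. 1 and 2, with 1767 and 2578 probes well above background, were left out of the marker means in this paragraph. Marker means above the highest Control array were 2.07 (week -3 No. 3) and 2.33 (week 6 No. 3) for macrophages, against 2.04, 0.22 for T and NK cells in week 6 No. 3 (-1.75), 1.72 for B and plasma cells in the same array (-1.15), -1.29 (week 2 No. 3) and -0.34 (week 6 No. 3) for neutrophils (-1.46), -2.74 (week -3 No. 3), -2.60 (week 2 No. 3) and -2.98 (week 2 No. 4) for squamous rumen epithelium (-3.00), and -3.04 (week 2 No. 4) and -2.64 (week 6 No. 3) for skeletal muscle (-3.19). Control week 2 No. 2 was left out of the highest Control value.

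Other splits of the same arrays were counted for each comparison, 100 for each with the real one included. For changes within Control, 1 of 100 splits gave as many genes as the real 102 from week -3 to week 2 (highest other 1) and 1 of 100 as many as the real 12 from week -3 to week 6 (highest other 1), and within SARA 1 of 100 as many as the real 2 (highest other 1) and 2 of 100 as many as the real 3 (highest other 75). Chance is thus an unlikely source of the Control counts. In SARA the first margin was 2 genes against 1, and another split gave 75 against the real 3. Chance was thus not excluded there. These splits did not keep slides fixed, so they cannot tell a change over weeks from an effect of slides. Splits that swap weeks within cows gave at most 35 and 0 genes in Control, and at most 1 and 1 over 64 splits in SARA. For the counts of 0, all 100 splits give as many by construction, so they say nothing about chance. The highest other splits gave 5, 1228, 1442 and 1009 genes for SARA against Control at weeks -3, 2 and 6 and in the average, 1096 and 265 from week 2 to week 6 in Control and SARA, and 0, 0 and 1 for the differences of changes. Such splits point to a structure of the samples. The split with 1228 genes placed 6 arrays of scan set 2 on 1 side and 0 of 7 on the other, that with 1442 placed 6 and 0 of 8, that with 1009 placed 15 of 23 and 3 of 22, and that with 1096 placed 7 and 1 of 7. Those with 265 and 75 genes placed 1 of 8 and 3 of 8, and 1 of 8 and 3 of 6, and so did not follow scan set. With scan set as a block the counts between the groups were 0, and those from week 2 to week 6 were 4 in Control and 1 in SARA.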

How the results depend on the processing

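The alternatives with scan set, with any libraries left out, and within each scan set were chosen after seeing the data; the others were fixed before. Counts of genes that passed are given as group and weeks (Control -3 to 2), as SARA-Control with its week, or as the difference between the groups' changes. Every count that moved by over 1.5 times is given, and so is the value of each gene, and the median log2 of each list, whose test turned its direction. In some lists the test turned while the median kept its sign. The cause was not tested, except that fits with fewer arrays or genes have fewer degrees of freedom or other genes to adjust over by construction.

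Under normexp background correction, the counts were 40 in Control -3 to 2 and 1 in SARA -3 to 6. Reversed were ANGPT1 0.17 (SARA -3 to 2), ASB15 0.058 (Control -3 to 2), cholesterol synthesis 0.13 (SARA-Control 2), mitochondrial fatty acid oxidation 0.12 (SARA -3 to 2), oxidative phosphorylation 0.043 (Control -3 to 2) and 0.040 (SARA -3 to 2), urea cycle and amino acid catabolism 0.17 (SARA-Control average) and xenobiotic metabolism 0.11 (SARA-Control average). Under quantile normalization, the counts were 7 in Control -3 to 6 and 1 in SARA 2 to 6. Reversed were oxidative phosphorylation 0.0054 (difference 2 to 6). With only probes well above background on all 45 arrays, the count was 1 in SARA-Control 6. It was 0 in SARA -3 to 2 and -3 to 6 (460 and 277 by limma at an unadjusted p under 0.05). With only the compared groups in the fit, the counts were 9 in Control -3 to 2, 65 in Control -3 to 6, 1 in SARA -3 to 2 and 0 in SARA -3 to 6 (468 by limma at an unadjusted p under 0.05). With the Non arrays added as groups, the counts were 9 in Control -3 to 2, 2 in Control -3 to 6, 0 in SARA -3 to 2 (317 by limma at an unadjusted p under 0.05) and 1 in SARA -3 to 6.

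With slide as a fixed block, Control had 11 for -3 to 2, 2 for -3 to 6 and 489 for 2 to 6. SARA had 0 for -3 to 2 and for -3 to 6 (967 and 889 by limma at an unadjusted p under 0.05). Reversed were macrophage and Kupffer cell markers 0.065 (Control -3 to 6) and mitochondrial fatty acid oxidation 0.0097 (SARA 2 to 6). With slide as a random block, the counts were 43 in Control -3 to 2, 2 in Control -3 to 6, 72 in Control 2 to 6, 1 in SARA -3 to 2, 1 in SARA -3 to 6 and 1 in SARA 2 to 6. For the cow as a random block, the counts were 393 in Control -3 to 2, 56 in Control -3 to 6, 86 in Control 2 to 6, 33 in SARA -3 to 2, 5 in SARA -3 to 6 and 3 in SARA 2 to 6. For the cow as a fixed replicate block (the pairing of 1 cow over weeks), the counts were 225 in Control -3 to 2, 37 in Control -3 to 6, 32 in SARA -3 to 2, 1 in SARA -3 to 6 and 3 in SARA 2 to 6.

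Without the library Control week 2 No. 2, the counts were 42 in Control -3 to 6, 1 in Control 2 to 6, 27 in SARA -3 to 2, 1 in SARA 2 to 6 and 1 in SARA-Control 6. Reversed were cholesterol synthesis -0.092 (SARA-Control 2), lipoprotein assembly and uptake -0.16 (Control 2 to 6), -0.11 (SARA-Control 2) and -0.025 (difference -3 to 2), hepatocyte markers 0.074 (Control -3 to 2) and 0.055 (difference -3 to 2) and xenobiotic metabolism -0.0018 (SARA-Control average). Without 4 libraries (SARA week -3 Nos. 3 and 4, SARA week 6 No. 8 and Control week 2 No. 2), the counts were 47 in Control -3 to 6, 1 in Control 2 to 6 and 17 in SARA -3 to 2. Reversed were cholesterol synthesis -0.092 (SARA-Control 2), lipoprotein assembly and uptake -0.16 (Control 2 to 6), -0.11 (SARA-Control 2) and -0.13 (difference -3 to 2), hepatocyte markers 0.074 (Control -3 to 2) and -0.096 (difference -3 to 2), skeletal muscle markers 0.45 (SARA -3 to 6), -0.26 (SARA-Control -3) and 0.56 (difference -3 to 6) and mitochondrial fatty acid oxidation -0.018 (difference -3 to 2).

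With scan set as a fixed block, the counts were 181 in Control -3 to 2, 19 in Control -3 to 6, 4 in Control 2 to 6, 8 in SARA -3 to 2 and 1 in SARA 2 to 6. Within scan set 1, the count in Control -3 to 2 was 5. It was 0 in Control -3 to 6, SARA -3 to 2 and SARA -3 to 6. There 423, 348 and 346 genes had an unadjusted p under 0.05 by limma. Reversed were cell cycle -0.023 (difference -3 to 6). Within scan set 2, the counts were 1706 in Control -3 to 2, 1578 in Control -3 to 6, 147 in Control 2 to 6, 1252 in SARA -3 to 2, 849 in SARA -3 to 6, 66 in SARA 2 to 6, 3 in SARA-Control 2, 548 in SARA-Control 6, 1 in difference -3 to 2 and 8 in difference 2 to 6. Reversed were acute phase proteins -0.075 (SARA-Control average), cell cycle -0.13 (SARA -3 to 2), cholesterol synthesis -0.079 (SARA-Control 2), lipoprotein assembly and uptake -0.019 (Control 2 to 6), endothelium markers -0.11 (SARA-Control -3) and -0.0057 (difference -3 to 2), hepatocyte markers 0.17 (Control -3 to 2), skeletal muscle markers 0.33 (SARA -3 to 2), 0.32 (SARA -3 to 6) and -0.22 (SARA-Control -3), mitochondrial fatty acid oxidation -0.041 (SARA-Control 2), triglyceride synthesis and lipid droplets 0.093 (SARA -3 to 2), urea cycle and amino acid catabolism -0.084 (SARA-Control average) and xenobiotic metabolism -0.058 (SARA-Control average).

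With scan set as a fixed block and that library left out, the counts were 162 in Control -3 to 2, 106 in Control -3 to 6, 1 in Control 2 to 6, 62 in SARA -3 to 2, 6 in SARA -3 to 6 and 3 in SARA 2 to 6. Reversed were cholesterol synthesis -0.051 (SARA-Control 2), lipoprotein assembly and uptake -0.22 (Control 2 to 6), -0.019 (SARA-Control 2) and -0.026 (difference -3 to 2), hepatocyte markers 0.068 (Control -3 to 2), mitochondrial fatty acid oxidation 0.055 (difference -3 to 2) and xenobiotic metabolism -0.023 (SARA-Control average). With slide as a fixed block and that library left out, the counts were 20 in Control -3 to 2, 5 in Control -3 to 6, 3 in Control 2 to 6, 10 in SARA -3 to 2 and 4 in SARA 2 to 6. Without that library and with a random cow block, the counts were 344 in Control -3 to 2, 283 in Control -3 to 6, 2 in Control 2 to 6, 192 in SARA -3 to 2, 41 in SARA -3 to 6, 52 in SARA 2 to 6 and 1 in difference 2 to 6. Without that library and with a fixed cow replicate block, the counts were 207 in Control -3 to 2, 269 in Control -3 to 6, 2 in Control 2 to 6, 161 in SARA -3 to 2, 35 in SARA -3 to 6 and 34 in SARA 2 to 6. Reversed were lipoprotein assembly and uptake -0.17 (Control 2 to 6) and -0.024 (difference -3 to 2), endothelium markers -0.0062 (difference 2 to 6), hepatocyte markers 0.075 (Control -3 to 2) and mitochondrial fatty acid oxidation 0.056 (difference -3 to 2).

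Of all counts, 192 stayed within 1.5 times of the values in the report and 88 did not. The genes that passed and were named, in 42 results, kept direction and side of the threshold in 621 values, kept direction and missed it in 280 and turned in 2. Named genes that had missed did so with the same sign in 3908 values, passed in 210 and changed sign without passing in 201. For lists called by the preset test the numbers were 3849, 770 and 61, with the fits that left out 1 library in turn among them. In these the interferon response ran from -0.030 to 0.43 in SARA 2 to 6. Without SARA week 6 Nos. 4 and 8, reversed were mitochondrial fatty acid oxidation -0.025 (SARA-Control 6) and -0.0021 (SARA 2 to 6), oxidative phosphorylation 0.036 (SARA-Control 6), 0.041 (difference -3 to 6) and -0.030 (difference 2 to 6), the cell cycle -0.021 (difference -3 to 6) and T and NK cell markers -0.14 (difference -3 to 6). The unfiltered probes, the mean over a gene's probes, the trended and robust variance, the series' value table and the cattle number as a block moved no count by over 1.5 times, and the last gave 0 genes at each week (563, 481 and 795 by limma at an unadjusted p under 0.05). The fixed cow block took CHIA to an adjusted p = 0.0566 and RELN to 0.0674 in Control -3 to 2, and PRKAR2A to 0.00933, PMM2 to 0.0463, UHRF1BP1 to 0.0474, JPH1 to 0.0397 and CL46 to 0.0397 in SARA -3 to 2, and CCND1 to 0.0256 in SARA 2 to 6. Of the preset list calls it ended those of macrophage markers in Control -3 to 6 (adjusted p = 0.0522), lipoprotein assembly (0.0694), T and NK cell markers (0.0603) and endothelium markers (0.0603) in Control 2 to 6, and peroxisomal oxidation (0.105), triglyceride synthesis (0.252), oxidative phosphorylation (0.115) and the cell cycle (0.0572) in SARA -3 to 2. In the differences it ended glycolysis (0.0538) and the cell cycle (0.0754) for -3 to 6 and endothelium markers (0.134) for 2 to 6, and added cholesterol synthesis (0.0451) and stellate cell markers (0.0090) for -3 to 2, urea cycle (0.0305) for -3 to 6 and stellate cell markers (0.0380) for 2 to 6. By fry it added adipocyte markers (0.0435) in Control -3 to 2 and glycolysis in Control -3 to 6 (0.00093) and SARA -3 to 2 (0.0329). Signal over background limits what can be read, since 7132 of 14953 genes were well above background on all fitted arrays.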

Other observations

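All values pooled over both groups, the splits of them, and the test within scan set 1 without Control week 2 No. 2 were chosen only after the data were seen, while the tests of the cell cycle genes in single cows and of the changes shared by both groups were set before their results were seen. The pooled fit held the cow as a fixed block and left out Control week 2 No. 2. From week -3 to week 2, 755 genes rose and 503 fell, from week -3 to week 6, 314 rose and 338 fell, and from week 2 to week 6, 11 rose and 157 fell. Within scan set 2 alone, where week and slide are confounded, 3325, 2354 and 378 genes passed. Within scan set 1 alone 104, 42 and 17 passed, and of the pooled calls, which those arrays are part of, 100%, 99.7% and 100% had the same direction there. At week 2 against week -3 the lipoprotein genes APOA4 (2.51 ± 0.36 (SE), adjusted p 4.0e-05) and APOA1 (1.54 ± 0.16) rose. So did MFSD2A, a transporter of lysophospholipids (2.25 ± 0.30), ANGPTL4, an inhibitor of lipoprotein lipase (1.26), CPT1A (0.73) and PC (1.07 ± 0.11). IGFBP2 rose by 1.38 while IGF1 (-1.12 ± 0.16) and its carrier subunit IGFALS (-1.19) fell, and so did the collectins SFTPD (-2.13), CGN1 (-2.09) and CL46 (-1.56) and the ornithine aminotransferase OAT (-1.14). In scan set 1 and scan set 2 taken alone APOA4 rose by 2.88 and 2.09, PC by 1.15 and 0.97, and IGF1 changed by -1.12 and -1.11. FGF21 (1.01, adjusted p 0.403) and HP (0.21, 0.910) did not pass.

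Week 6 against week -3 showed a fall in AK4 (-2.81 ± 0.23, adjusted p 1.1e-08, and -2.87 and -2.69 in the scan sets alone). GDF15 (-1.81), A2M (-1.50) and FETUB (-1.47) fell too. VNN1, which releases pantothenate (1.80), and G6PC1, the last step of glucose release (0.74), rose. So did PCK1 (0.96) and the urea cycle genes ASL (0.71), ARG1 (0.78) and ASS1 (0.49). From week 2 to week 6 CCND1 (-1.26 ± 0.14, adjusted p 8.0e-06), ELOVL2 of fatty acid elongation (-1.18), APOA1 (-1.07), ANGPTL4 (-0.86) and CPT1A (-0.54) fell. Of the lists, lipoprotein assembly rose by a median of 0.21 from week -3 to week 2 (7 genes up and 1 down, 8 and 1 adjusted over the list alone) and fell by 0.18 from week 2 to week 6 (0 and 4, 1 and 7 adjusted over the list alone). With an estimated correlation it passed from week 2 to week 6 (adjusted p 0.046) and missed from week -3 to week 2 (0.080), where fry gave 5.4e-06. With the preset correlation gluconeogenesis (0.19), mitochondrial fatty acid oxidation (0.24), glycolysis (0.15), triglyceride synthesis (0.25), peroxisomal oxidation (0.19), cholesterol synthesis (0.27), oxidative phosphorylation (0.12) and cell cycle (0.73) also rose from week -3 to week 2. Extracellular matrix (-0.20) and the markers of stellate cells (-0.33), T and NK cells (-0.29) and skeletal muscle (-0.62) fell, the last by a pooled value that includes SARA week -3 Nos. 3 and 4 and that was -1.97 in scan set 1 but 0.48 in scan set 2. None of these passed once the correlation was estimated, with adjusted p from 0.347 to 0.707. By fry, adjusted p were 0.0069 for gluconeogenesis, 0.0098 for mitochondrial fatty acid oxidation, 0.00024 for glycolysis, 0.0070 for triglyceride synthesis and 0.030 for peroxisomal oxidation, and 0.199 for cholesterol synthesis and oxidative phosphorylation, 0.060 for cell cycle, 0.144 for extracellular matrix, 0.128 for stellate cells, 0.325 for T and NK cells and 0.328 for skeletal muscle. For week 6 against week -3 the preset correlation called gluconeogenesis (0.16, fry 0.017), glycolysis (0.13, fry 0.0092), mitochondrial fatty acid oxidation (0.11), cholesterol synthesis (0.18), oxidative phosphorylation (0.081) and urea cycle (0.13) higher, and extracellular matrix (-0.17) and the markers of macrophages (-0.30) and stellate cells (-0.24) lower, with adjusted p by fry from 0.218 to 0.380 for the lists whose fry value is not given. For week 6 against week 2 it called the cell cycle lower (-0.62, fry 0.181, 13 genes down adjusted over the list alone, -0.93 and -0.15 in scan sets 1 and 2) and the urea cycle higher (0.14, fry 0.718). With an estimated correlation none of these passed, with adjusted p from 0.382 to 0.930.

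For weeks -3 to 2, -3 to 6 and 2 to 6 the real counts were 1258, 652 and 168. Splits that swap weeks within cows gave as many genes in 1, 2 and 1 of 100 (highest other 208, 936 and 23). Chance is thus an unlikely source of the first and last counts. For week -3 to week 6 another split gave more genes than the real one, so chance was not excluded there. Such swaps cannot tell a change over weeks from an effect of slides.

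Cell cycle genes were higher on average at week 2 than at week -3 in 76.9% of the 13 cows with both weeks, 6 of 7 Control and 4 of 6 SARA, and in 9 of 12 without Control week 2 No. 2. A rise carried by a few cows cannot be told apart from one in most cows at this number. The median change was 0.49, and 12 of 15 cows were lower at week 6 than at week 2.

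Across 11901 genes, which are not independent replicates, the changes from week -3 to week 2 in Control and in SARA had a correlation of 0.306 (Spearman 0.329, 63.2% of genes in the same direction), 0.438 without Control week 2 No. 2, and those from week -3 to week 6 had 0.383. A change around calving shared by both groups may account for this. Slides of scan set 2 that hold 1 week of both groups were the other source weighed. Within scan set 1 the correlation was 0.352 from week -3 to week 6, which argues against the slides of scan set 2 as the whole source. From week -3 to week 2 it was 0.114, which leaves those slides open, but 0.328 without Control week 2 No. 2, which argues against them. The slides of scan set 1 were not weighed and stay open as a source. There the SARA arrays of week -3 lay on slides 1 and 3 and those of week 6 on slides 2 and 4. Control arrays of weeks -3 and 6 shared only slide 3 there. In scan set 2 the correlations were 0.554 from week -3 to week 2 and 0.268 from week -3 to week 6. From week 2 to week 6 the correlation was 0.023 over all arrays and 0.130 without Control week 2 No. 2.

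Among lists that the preset test called in none of the 13 comparisons, medians in Control from week -3 to week 2 were -0.28 for the circadian clock, -0.012 for the antioxidant response, and, for markers, 0.020 for neutrophils, 0.066 for B and plasma cells, 0.25 for cholangiocytes, -0.18 for erythroid blood cells, 0.31 for squamous rumen epithelium and 0.17 for adipocytes. Without Control week 2 No. 2 they were, in the same order, -0.14, -0.024, 0.087, 0.055, -0.095, 0.11, 0.14 and 0.23.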
